A study of Rattus norvegicus with 56 samples.

How the data were processed

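The series holds 56 Affymetrix rat arrays of total RNA from lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of adult Wistar rats. Ganglia were taken 3, 7, 21 or 40 days after 1 of 3 lesions of the sciatic nerve or its roots, after a sham operation, or from naive animals. The sample labels give the times in days while the series design text gives the same numbers in hours, and the days were used. The growth protocol in the labels speaks of a crush lesion, which none of the group labels name. Labels call the arrays of a group biological replicates and do not say whether ganglia of several animals were pooled, so p-values measure the spread between these samples.

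The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and summary of the probes of a set) per the submitters' processing notes. The RMA version, and whether all arrays were processed in a single run, are not given in the sources used here. Array medians of the deposited log2 values lay between 6.19 and 6.36 and array means between 6.30 and 6.41, so the distributions were close but not identical. A quantile step run last over all 56 arrays would have made them identical. The number of arrays limits the precision of every value, since no probe-level signal or background was used here.

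The table holds 8799 probe sets, of which 59 are array controls and were left out. Names came from the platform annotation supplied with the values, with symbols looked up through Entrez identifiers in a RefSeq gene table of the rat assembly GRCr8. There were 7018 probe sets with 1 gene symbol, 308 with several and 1473 unnamed here, and 6994 of the first kind had their Entrez identifier in the gene table, where 0 symbols needed an update. For the 1565 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene. Probe sets with several symbols or none were tested but are not named. This left 6470 tested features, 4736 of them named genes. Among 59 named calls in genes with more than 1 probe set, 6 had another probe set of opposite sign, in Rab11b, Tubb2b, Fn1, Kcnc2 and Gch1.

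Tests used limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to the log2 values of all 56 arrays (lmFit, eBayes), so that groups of 2 or 3 arrays shared 1 estimate of the spread, with 37 residual degrees of freedom. Contrasts compared SNI and Ch with the sham arrays of the same lesion and day, and CCI with naive arrays because no sham of that lesion is labelled. The main comparison of each lesion was the mean of its contrasts at days 3, 7 and 21. Arrays at day 40 were compared with naive arrays, as no sham is labelled for that day. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Adjusted p-values in the text come from limma unless another test is named, ± is the standard error of a log2 change or the SD of a group's log2 values, and fold sizes are 2 to the power of the log2 change.

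The text names genes by a rule. For each main comparison it takes the 10 largest rises and 10 largest falls among called genes with the same sign at each of the 3 days. For every other contrast it takes the 5 largest of each, and Kcns1 is given everywhere. From the lists it takes up to 4 called members per list and contrast, and up to 2 members of the highest level where fewer than 2 were called. The uncalled members of highest level were left unnamed except in the muscle list, and their values are not followed through the alternatives. That departure from the rule was decided after the alternatives had been seen, in which many of these uncalled genes changed sign. Of genes called in all 3 lesions, up to 10 per direction were taken. There were 21 gene lists, with 422 members measured and 15 of these in more than 1 list. They covered injury and regeneration genes, potassium channels, sodium, calcium and HCN channels, sensory neuron peptides and receptors, neurofilaments and neuronal cytoskeleton, transmitter receptors, satellite glia, Schwann cell myelin, macrophages, lymphocytes, antigen presentation and complement, extracellular matrix and fibroblasts, endothelium and pericytes, blood cells, skeletal muscle, adipose tissue, cell cycle, cholesterol synthesis, tetrahydrobiopterin, heat shock and unfolded protein, and oxidative phosphorylation. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 63 tests, and again with an estimated correlation. The groups, contrasts, rule, lists and the alternative settings named first below were fixed before the data were examined.

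The procedure was tested on simulated data with the real genes' means and spreads and 200 changed genes among 6470, in 5 runs. For the SNI mean contrast, 93.6% of genes changed by 0.5 on the log2 scale were called, 99.2% of those changed by 1.0, and 3.75% of calls were false. For SNI at day 3, 59.3% of genes changed by 0.5 and 94.5% of those changed by 1.0 were called, with 4.51% false. The simulated values were independent between genes and arrays, with no arrays that stood apart, so these rates need not hold for the real data. The alternative settings fixed beforehand were the mean of all probe sets of a gene, removal of probe sets with a log2 mean of 5.03 or less, another quantile normalization over all arrays, the replicate number as a block, a fit to the arrays of the contrast alone, the other control, and each array left out in turn. Settings added after the data were seen were a term for 9 arrays of low mean level, those arrays left out, 3 arrays whose injury list mean went against their labels left out, and the mean of the muscle list as a term.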

Results

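The arrays measured gene expression in L4 and L5 dorsal root ganglia of rats after 3 kinds of nerve lesion used as models of chronic pain. In the spared nerve injury (SNI) branches of the sciatic nerve are cut and another branch is left intact. In the chronic constriction injury (CCI) loose ligatures are tied around the sciatic nerve. The spinal nerve ligation, called Ch in the labels and here, ties off a spinal nerve close to the ganglion. SNI and CCI had 12 arrays each and Ch had 11, spread over days 3, 7, 21 and 40, with 3 arrays per group except 2 for Ch at day 21. SNI and Ch had 9 sham arrays each, at days 3, 7 and 21, and 3 arrays came from naive rats. Correlations between arrays lay between 0.964 and 0.997, and 2 arrays of a group shared exactly equal values in at most a fraction of 1.14e-04 of the probe sets. A set of 9 arrays had a mean log2 level between 6.30 and 6.34 while the other 47 lay between 6.37 and 6.41, and 4 of those 9 were Ch sham arrays.

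After SNI, injury and regeneration genes rose, in 18, 19 and 14 of 37 cases at days 3, 7 and 21, and potassium channel genes were among those that fell. The neuropeptide gene Npy rose by 3.34 ± 0.31 on the log2 scale (SE, 9 lesioned and 9 sham arrays), a 10.1-fold change with an adjusted p of 2.74e-10. Reg3b, a secreted lectin, rose by 3.10 ± 0.29, the neuropeptide gene Gal by 3.05 ± 0.26, and Atf3, a transcription factor induced by stress and axon injury, by 2.97 ± 0.28. All 9 lesioned arrays lay above all 9 sham arrays for each of these genes. Vip, another neuropeptide, rose by 2.38 ± 0.35, the protease inhibitor Serpina3n by 1.78 ± 0.21, the growth arrest gene Gadd45a by 1.52 ± 0.21, and C9h6orf141 by 1.50 ± 0.20. Gch1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, rose by 1.62 ± 0.19. The other probe sets of Gch1 had 0.71, 0.02 and 0.002, so the size of its rise rests on 1 probe set. The calcium channel subunit gene Cacna2d1, whose product binds gabapentin, rose by 1.42 ± 0.19. Among named genes the largest fall was that of Kcns1, a potassium channel subunit that modifies other channels, at −0.76 ± 0.19 with an adjusted p of 0.00826. Further falls were Kcnk1, a background potassium channel, at −0.69 ± 0.09, Kcns3 at −0.68 ± 0.19 and the calcium sensor Vsnl1 at −0.67 ± 0.20. The synaptic genes Snap25 and Rab3a fell by 0.61 ± 0.14 and 0.57 ± 0.17. Falls were also seen for Rapgef4 by 0.57 ± 0.17, the adhesion gene Cadm1 by 0.57 ± 0.16, the potassium channel auxiliary gene Dpp6 by 0.56 ± 0.14, and Pvalb by 0.59 ± 0.20. Pvalb encodes a calcium-binding protein of sensory neurons and fast muscle. In all, 569 features passed the test in the SNI mean contrast, with 348 rises and 221 falls. Of 63 called genes named for this contrast, 53 moved in the same direction in each of the 9 lesioned arrays and the others in at least 7.

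By gene group, 26 of 37 measured injury and regeneration genes rose after SNI and 0 fell, or 27 rose when adjusted over the list alone. The list's camera adjusted p was 4.73e-37, and its adjusted p = 0.0171 with an estimated correlation was the single such value under 0.05 among the 63 list tests. Among potassium channel genes 11 of 45 fell and 0 rose, 14 fell adjusted over the list alone, and the members included Kcnab1 at −0.50 ± 0.12. Potassium channels had a camera adjusted p of 7.19e-07, and adjusted p = 0.135 with an estimated correlation. Antigen presentation and complement genes rose in 15 of 21 cases, led by the class II genes RT1-Da at 1.20 ± 0.17 and Cd74 at 1.18 ± 0.16 and the complement gene C1qb at 1.16 ± 0.16, with RT1-DMb at 0.84 ± 0.14. Adjusted over the list alone 17 rose and 1 fell, and the camera adjusted p was 3.72e-14 (adjusted p = 0.0671 with an estimated correlation). Macrophage markers rose in 9 of 17 cases, 9 also adjusted over the list alone, including the lysozyme gene Lyz2 at 1.05 ± 0.14 and the protease Ctss at 1.01 ± 0.18. Macrophage markers had a camera adjusted p of 4.69e-09, and adjusted p = 0.0671 with an estimated correlation. Of 20 extracellular matrix and fibroblast markers 5 rose, 10 adjusted over the list alone, with Postn at 0.70 ± 0.19, Timp1 at 0.69 ± 0.11, Fn1 at 0.50 ± 0.15 and Mmp3 at 0.46 ± 0.09. The other probe sets of Fn1 had −0.19, −0.14, −0.07 and −0.09 after SNI, so its rise rests on 1 probe set. Matrix genes had a camera adjusted p of 1.81e-07, and adjusted p = 0.137 with an estimated correlation. Neurofilament and neuronal cytoskeleton genes rose in 6 of 22 cases (list median 0.01), 7 adjusted over the list alone, among them Stmn4 at 1.23 ± 0.15, Gap43 at 0.83 ± 0.11, Tubb2b at 0.63 ± 0.07 and Basp1 at 0.47 ± 0.08. Cytoskeleton genes had a camera adjusted p of 0.00805, and adjusted p = 0.221 with an estimated correlation.

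Sensory neuron peptide and receptor genes fell in 6 of 34 cases after SNI, including the neurotrophin receptor gene Ngfr at −0.35 ± 0.07, Adra2c at −0.29 ± 0.06 and the capsaicin receptor gene Trpv1 at −0.28 ± 0.09, while the growth factor receptor gene Gfra1 rose by 1.03 ± 0.13. Adjusted over the list alone 8 fell and 1 rose. Sensory neuron genes had a camera adjusted p of 0.025, and adjusted p = 0.446 with an estimated correlation. Transmitter receptor genes fell in 4 of 45 cases, 4 adjusted over the list alone, namely Gabbr2 at −0.49 ± 0.10, Grm4 at −0.43 ± 0.07, Gria2 at −0.29 ± 0.07 and Gabra2 at −0.26 ± 0.08. Transmitter receptors had a camera adjusted p of 2.20e-04, and adjusted p = 0.186 with an estimated correlation. Of 23 oxidative phosphorylation genes 9 fell, 10 adjusted over the list alone, with the complex I genes Ndufs1 at −0.46 ± 0.15, Ndufv2 at −0.40 ± 0.10, Ndufa8 at −0.40 ± 0.11 and Ndufa9 at −0.39 ± 0.10. Oxidative phosphorylation had a camera adjusted p of 3.67e-06, and adjusted p = 0.135 with an estimated correlation. Skeletal muscle genes had a camera adjusted p of 0.0131 toward lower levels (adjusted p = 0.605 with an estimated correlation), although Pvalb alone of 19 members fell and 0 passed adjusted over the list alone. Acta1 and Ckm, the muscle genes of highest level, had −0.48 ± 0.43 and −0.53 ± 0.39 and did not pass. In lists that camera did not call after SNI, the members that passed were Cacna2d1, Scn3a at 0.31 ± 0.06 and Scn8a at −0.26 ± 0.07 among sodium, calcium and HCN channels (camera adjusted p = 0.822). Satellite glia markers that passed were Entpd2 at 0.41 ± 0.09, Vim at 0.32 ± 0.07 and Cadm1 (list value 0.822). Those of Schwann cell myelin were Mbp at −0.33 ± 0.10 and Mag at −0.21 ± 0.07 (list value 0.137). Gzmb at 0.37 ± 0.11 passed among lymphocyte markers (0.999), Mcm5 at 0.25 ± 0.07 among cell cycle genes (0.378). Tetrahydrobiopterin genes that passed were Gch1, Spr at 0.54 ± 0.08 and Qdpr at 0.30 ± 0.08 (0.204). Heat shock genes that passed were Hspb1 at 0.81 ± 0.09 and Hsph1 at −0.36 ± 0.08 (0.724). No member passed among endothelial and pericyte markers (0.986), blood cell genes (0.986), adipose genes (0.569) or cholesterol synthesis genes (0.983). The list median, list mean and test differed in sign after SNI for sodium, calcium and HCN channels, endothelial markers, blood cell genes, cholesterol synthesis, tetrahydrobiopterin and heat shock genes. With naive arrays as the control the SNI count was 240, the channel list had a camera adjusted p of 0.0654, the sensory neuron list 0.254 and the transmitter receptor list 0.301. There the muscle list turned to higher at 0.995.

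**Figure D1:**
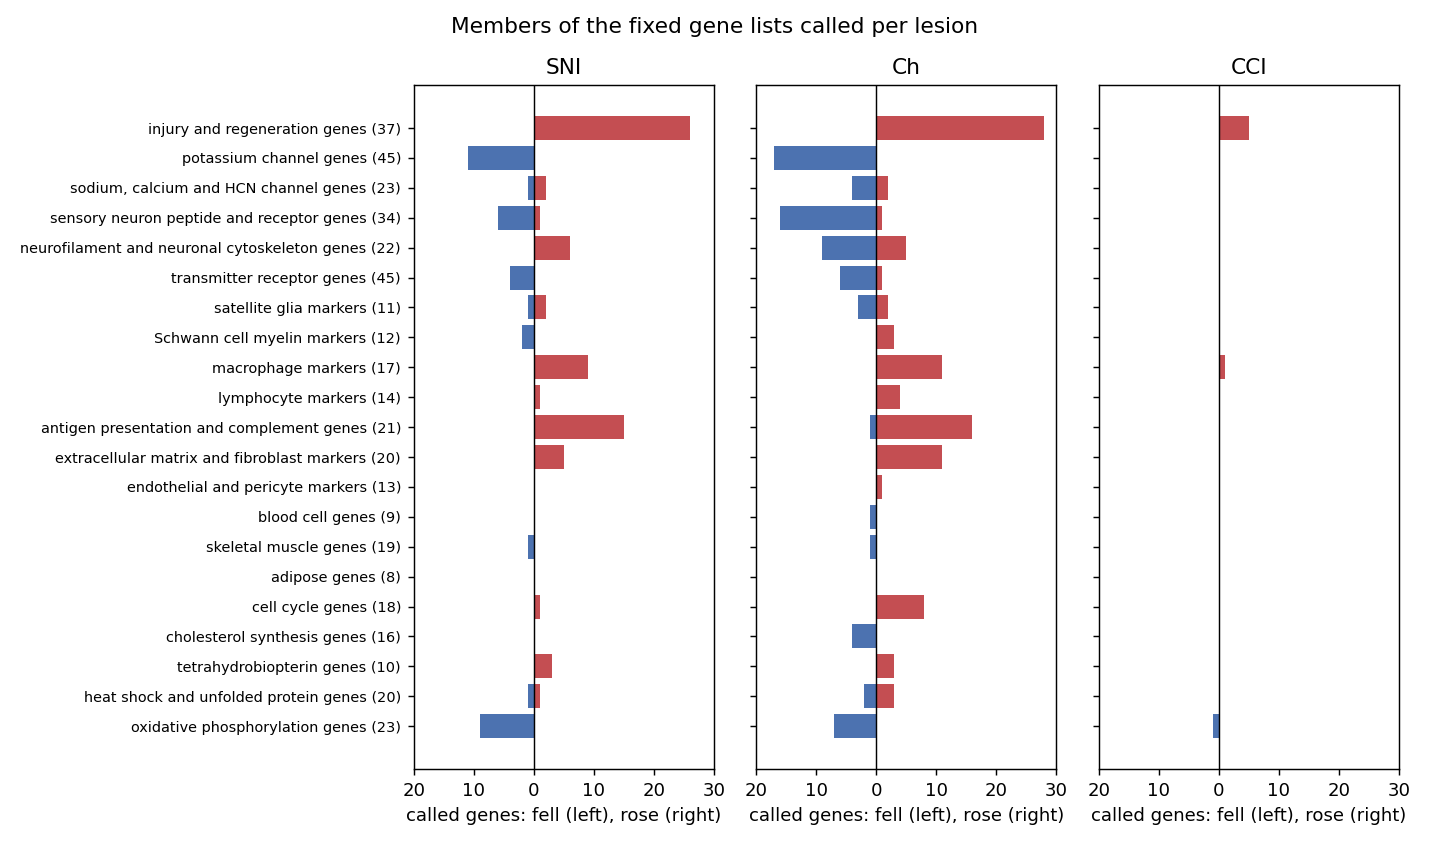
Number of called genes per fixed gene list in the mean contrasts of SNI, Ch and CCI, with bars to the right for genes that rose and to the left for genes that fell, and the number of measured members in parentheses. Injury and regeneration genes rose in 26, 28 and 5 of 37 cases, and potassium channel genes fell in 11, 17 and 0 of 45. CCI was set against 3 naive arrays, and SNI and Ch against 9 sham arrays each, so the counts are not at equal power.

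At single days SNI called 65 features at day 3 (53 rises, 12 falls), 153 at day 7 (99 and 54) and 43 at day 21 (39 and 4). Atf3 was the largest rise at day 3 with 3.19 ± 0.49, against 2.90 ± 0.49 at day 7 and 2.83 ± 0.49 at day 21. Npy rose by 2.48 ± 0.53 at day 3, 3.64 ± 0.53 at day 7 and 3.89 ± 0.53 at day 21, and Vip was among the largest rises at day 7 (2.48 ± 0.61) and day 21 (2.54 ± 0.61). Gal rose by 3.02 ± 0.46, 2.95 ± 0.46 and 3.17 ± 0.46, and Reg3b by 2.72 ± 0.51, 3.18 ± 0.51 and 3.39 ± 0.51, at days 3, 7 and 21. Gch1 rose by 2.01 ± 0.33 at day 3. Kcnk1 fell by 0.77 ± 0.16, 0.69 ± 0.16 and 0.62 ± 0.16 at days 3, 7 and 21. The other largest falls were Gabbr2 (−0.70 ± 0.17), Fgf9 (−0.62 ± 0.14), Tle4 (−0.60 ± 0.13) and Fgf18 (−0.58 ± 0.11) at day 3. At day 7 they were Rasgrp1 (−1.24 ± 0.22), Pctp (−0.80 ± 0.17), Nexn (−0.74 ± 0.18) and Htr1d (−0.69 ± 0.16), and at day 21 Tdp1 (−0.46 ± 0.10) and Rsph1 (−0.42 ± 0.10). Whether the SNI effect differed between days 21 and 3 was tested directly, and limma called 0 features, with 222 at an unadjusted p under 0.05 and 1 called in a fit to those arrays alone. Leaving out single arrays gave 26 to 60 calls at day 3, 40 to 185 at day 7 and 14 to 25 at day 21.

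After Ch, 28 of 37 injury and regeneration genes rose, and 16 of 34 sensory neuron peptide and receptor genes and 17 of 45 potassium channel genes fell. At an estimated correlation none of these 3 lists had an adjusted p under 0.05 after Ch (0.0534, 0.0671 and 0.0858). Reg3b rose by 2.99 ± 0.30 (SE, 8 lesioned and 9 sham arrays, adjusted p = 2.13e-09), Npy by 2.40 ± 0.32, Atf3 by 2.26 ± 0.29, Gal by 2.20 ± 0.27 and Vip by 2.13 ± 0.37. The chemokine gene Cxcl14 rose by 1.83 ± 0.31, Serpina3n by 1.65 ± 0.22, Gadd45a by 1.62 ± 0.22, C9h6orf141 by 1.61 ± 0.21 and the membrane metalloprotease Mmp16 by 1.53 ± 0.16. Among named genes the largest fall was that of Sst, the somatostatin gene of a class of small sensory neurons, at −2.08 ± 0.21, a 4.21-fold change with an adjusted p of 2.13e-09. The kainate receptor gene Grik1 fell by 1.74 ± 0.23, the nociceptor sodium channel gene Scn11a by 1.67 ± 0.17, the neurite growth gene Nrn1 by 1.62 ± 0.20 and Kcns1 by 1.59 ± 0.20. Falls also reached 1.57 ± 0.18 for the potassium channel Kcnd3, 1.56 ± 0.15 for the serotonin receptor Htr3a, 1.52 ± 0.19 for Kcns3, 1.49 ± 0.17 for the phospholipase Plcd4 and 1.48 ± 0.19 for the secretogranin Scg2. The other probe sets of Kcnd3 had −0.25 and −0.18 after Ch, so the size of its fall rests on 1 probe set. The Ch mean contrast called 1157 features, 700 rises and 457 falls. Of 79 called genes named for it, 43 moved in the same direction in each of the 8 lesioned arrays, and the fewest arrays for any of them was 6.

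Injury and regeneration genes rose in 28 of 37 cases after Ch, 29 adjusted over the list alone, and 0 fell. Injury genes had a camera adjusted p of 1.34e-26, and adjusted p = 0.0534 with an estimated correlation. Potassium channel genes fell in 17 of 45 cases and 0 rose, 18 adjusted over the list alone, with Kcnc2 at −0.83 ± 0.18 after the genes named above. Potassium channels had a camera adjusted p of 4.69e-09, and adjusted p = 0.0858 with an estimated correlation. Sensory neuron peptide and receptor genes fell in 16 of 34 cases, including the calcitonin gene-related peptide gene Calcb at −1.05 ± 0.15, and Gfra1 rose by 1.05 ± 0.13. Adjusted over the list alone 17 fell and 2 rose. Sensory neuron genes had a camera adjusted p of 6.59e-08, and adjusted p = 0.0671 with an estimated correlation. Among sodium, calcium and HCN channels 4 of 23 fell, with Scn10a at −1.35 ± 0.16 and Scn1a at −1.34 ± 0.17 beside Scn11a, and 2 rose, with Cacna2d1 at 1.38 ± 0.20. Adjusted over the list alone 5 fell and 2 rose, and the list's camera adjusted p was 0.0588. Transmitter receptor genes fell in 6 of 45 cases and rose in 1, against 5 and 1 adjusted over the list alone, with Chrna3 at −1.22 ± 0.16, Gabbr2 at −0.73 ± 0.10 and Gabrb2 at −0.38 ± 0.12. Transmitter receptors had a camera adjusted p of 0.025, and adjusted p = 0.458 with an estimated correlation. Neurofilament and cytoskeleton genes went both ways, with 5 of 22 rising (Stmn4 at 1.12 ± 0.16, Gap43 at 0.75 ± 0.11) and 9 falling (Dpysl4 at −0.98 ± 0.12, the light neurofilament gene Nefl at −0.65 ± 0.09), and a camera adjusted p of 0.0697. Adjusted over the list alone 5 rose and 11 fell.

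Macrophage markers rose after Ch in 11 of 17 cases, 12 adjusted over the list alone, including C1qb at 1.23 ± 0.17, Fcgr2b at 1.04 ± 0.16, Ctss at 0.99 ± 0.19 and the chemokine Ccl2 at 0.92 ± 0.12. Macrophage markers had a camera adjusted p of 1.10e-09, and adjusted p = 0.0671 with an estimated correlation. Antigen presentation and complement genes rose in 16 of 21 cases, 17 adjusted over the list alone, with C3 at 0.90 ± 0.17 and RT1-Da at 0.86 ± 0.18, while the complement inhibitor Cd55 fell by 1.10 ± 0.17. Antigen presentation genes had a camera adjusted p of 6.99e-10, and adjusted p = 0.135 with an estimated correlation. Matrix and fibroblast markers rose in 11 of 20 cases, 14 adjusted over the list alone, with Timp1 at 0.75 ± 0.12, Fn1 at 0.72 ± 0.16, Mmp2 at 0.60 ± 0.13 and Mmp3 at 0.54 ± 0.09. The other probe sets of Fn1 had −0.04, 0.09, 0.33 and −0.05 after Ch. Matrix genes had a camera adjusted p of 7.21e-08, and adjusted p = 0.135 with an estimated correlation. Cell cycle genes rose in 8 of 18 cases, 10 adjusted over the list alone, with Top2a at 0.71 ± 0.13, Cdk1 at 0.67 ± 0.12, Cdk4 at 0.51 ± 0.10 and Mcm5 at 0.50 ± 0.08. Cell cycle genes had a camera adjusted p of 2.09e-04, and adjusted p = 0.135 with an estimated correlation. Oxidative phosphorylation genes fell in 7 of 23 cases, 10 adjusted over the list alone, with Atp5f1a at −0.41 ± 0.08, Sdha at −0.29 ± 0.09 and Ndufb9 at −0.27 ± 0.07. Oxidative phosphorylation had a camera adjusted p of 3.22e-06, and adjusted p = 0.135 with an estimated correlation. Camera did not call the remaining lists after Ch. The 5 called members of the satellite glia list included Fabp7 (−0.63 ± 0.12), Cadm1 (−0.56 ± 0.17), Entpd2 (0.47 ± 0.09) and Vim (0.31 ± 0.08) (camera adjusted p = 0.345). Schwann cell members were Egr2 (0.63 ± 0.12), Cnp (0.47 ± 0.11) and Sox10 (0.46 ± 0.11), with 0.0912. Lymphocyte markers had Gzmb (0.89 ± 0.12), Cd3g (0.26 ± 0.09), Cd4 (0.26 ± 0.08) and Cd247 (0.20 ± 0.06) with a list value of 0.0992. Tetrahydrobiopterin genes had Gch1 (1.45 ± 0.20), Spr (0.75 ± 0.08) and Qdpr (0.44 ± 0.08) with 0.11. The other probe sets of Gch1 had 0.93, −0.03 and 0.06 after Ch. Called heat shock genes included Hspa2 (0.71 ± 0.14), Hspb1 (0.58 ± 0.09), Hsph1 (−0.55 ± 0.09) and Pdia4 (0.31 ± 0.08), with a list value of 0.724. Cholesterol synthesis genes fell in 4 of 16 cases, Cyp51 (−0.38 ± 0.11), Sqle (−0.29 ± 0.09), Insig1 (−0.29 ± 0.07) and Fdft1 (−0.20 ± 0.06), with a list value of 0.292. Single members passed among endothelial markers (Abcb1b, 0.24 ± 0.08, list value 0.751), blood cell genes (Car2, −0.88 ± 0.16, 0.345) and muscle genes (Pvalb, −1.05 ± 0.20, 0.939), and 0 among adipose genes (0.671). Acta1 and Ckm had 0.80 ± 0.45 and 0.45 ± 0.40 after Ch and did not pass. The list median, mean and test differed in sign after Ch for adipose, cholesterol synthesis and tetrahydrobiopterin genes.

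The injury list mean, Atf3 and Kcns1 of 3 Ch arrays went against their labels. The array labelled Ch sham day 7 replicate 1 had Atf3 at 9.87 and Kcns1 at 6.57, while the arrays labelled Ch day 3 replicate 2 and Ch day 40 replicate 3 had Atf3 at 8.21 and 7.79 and Kcns1 at 7.95 and 8.09. Not every gene went this way. Serpina3n was 6.91 in that sham array, among the other Ch shams (6.51 to 7.04), and 7.31 in Ch day 3 replicate 2, among the other lesioned Ch arrays (7.29 to 9.28). Ccl2 was 9.005 in Ch day 3 replicate 2, also among them (8.37 to 9.24). For these genes, Reg3b and Spr every lesioned Ch array of days 3 to 21 lay above every Ch sham array, while Ch day 40 replicate 3 lay among the shams for all 4. These 4 genes were picked for that separation by label, so they decide nothing by themselves. Reg3b and Spr of the array labelled Ch sham day 7 replicate 1 (7.59 and 7.80) lay above the other Ch shams (up to 5.74 and 7.635). They came close to Ch day 3 replicate 2 (7.69 and 7.81). Without the 3 arrays that went against their labels, an alternative added after the data were seen, the Ch mean contrast called 1558 features, of which 1150 were called in the same direction with them. The Ch count was 337 without the low-level arrays, where the array labelled Ch sham day 7 replicate 1 was the only sham array of its day, and 748 in a fit to its own arrays, and with a term for the low-level arrays it split into 530 rises and 525 falls.

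**Figure D2:**
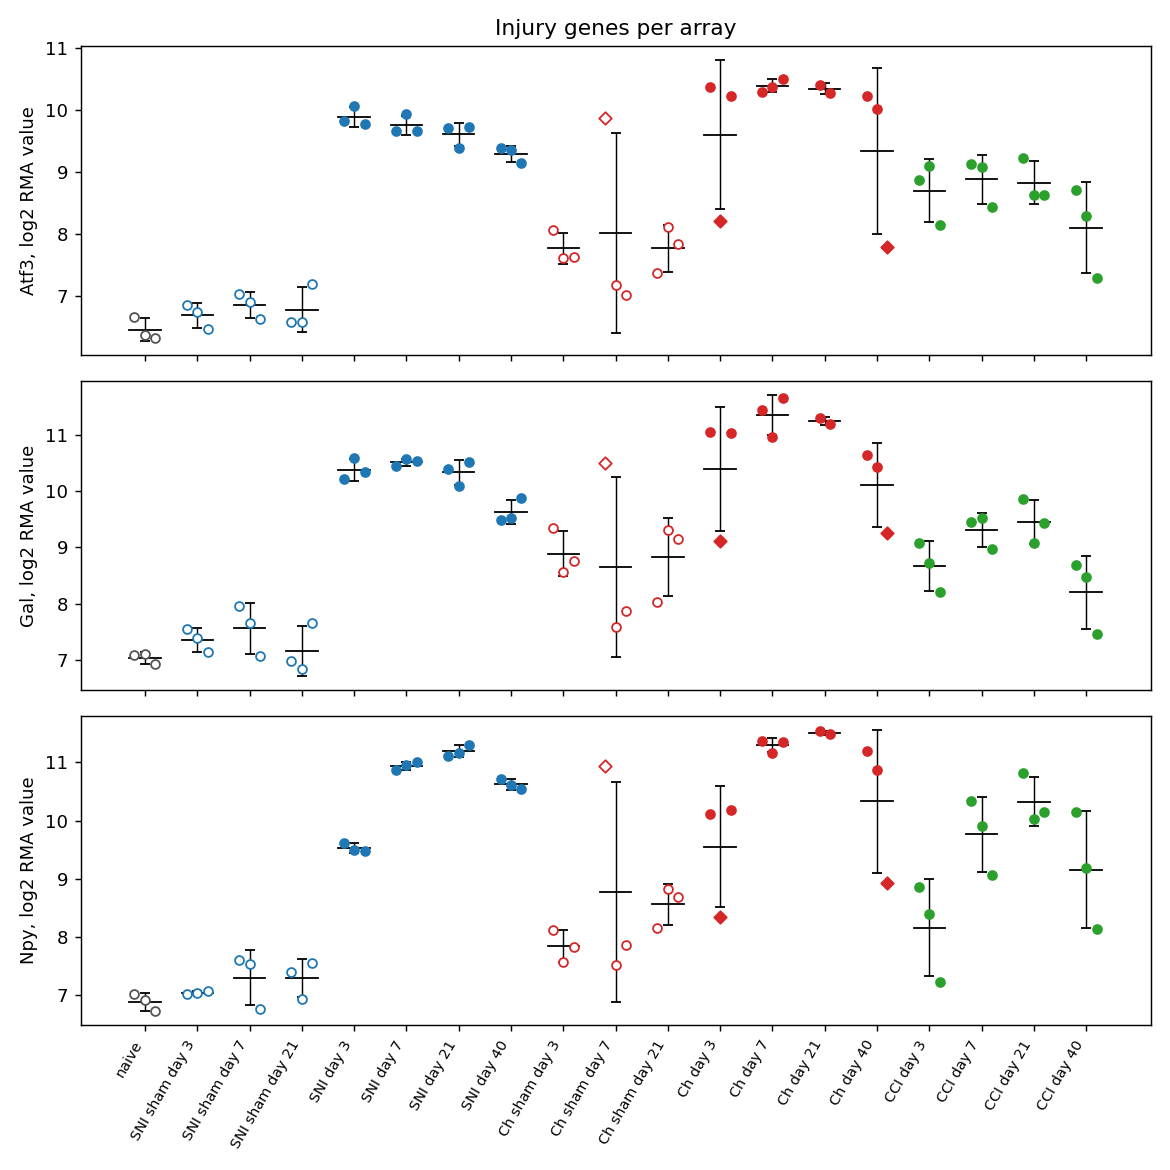
Log2 RMA values of Atf3, Gal and Npy per array and group, with open symbols for naive and sham arrays, filled symbols for lesioned arrays, diamonds for the 3 Ch arrays whose injury list mean went against their labels, and a bar with error bars for the group mean and SD. The 9 lesioned SNI arrays of days 3 to 21 lie between 9.38 and 10.06 for Atf3 and the SNI sham arrays between 6.47 and 7.19.

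By day, Ch called 132 features at day 3 (49 rises, 83 falls), 460 at day 7 (306 and 154) and 611 at day 21 (372 and 239). At day 3 the largest falls were Ppp1r1a (−1.92 ± 0.38), Sst (−1.63 ± 0.35), Plcd4 (−1.63 ± 0.29), Scn11a (−1.58 ± 0.28) and Grik1 (−1.57 ± 0.38). The largest rises were Reg3b (2.67 ± 0.51), Atf3 (1.83 ± 0.49), the stress-induced muscle and nerve gene Ankrd1 (1.41 ± 0.30), Serpina3n (1.34 ± 0.37) and Csrp3 (1.18 ± 0.30). At day 7 Reg3b rose by 2.86 ± 0.51, Gal by 2.69 ± 0.46, Npy by 2.52 ± 0.53 and Atf3 by 2.37 ± 0.49. The skeletal muscle actin gene Acta1 was among the largest rises at 2.69 ± 0.75, with a muscle list median of 1.16, and with the mean of the muscle list as a term it had 0.68 ± 0.25 and did not pass. Sst (−1.81 ± 0.35), Vsnl1 (−1.61 ± 0.34), Grik1 (−1.50 ± 0.38), Kcns1 (−1.50 ± 0.33) and Nrn1 (−1.42 ± 0.34) fell most at that day. At day 21 Reg3b (3.43 ± 0.57), Vip (3.24 ± 0.68), Npy (2.95 ± 0.60), Atf3 (2.57 ± 0.54) and Gal (2.41 ± 0.51) rose most. The largest falls at day 21 were Sst (−2.78 ± 0.39), Pvalb (−2.74 ± 0.38), Htr3a (−2.32 ± 0.28), Kcns1 (−2.17 ± 0.37) and Scg2 (−2.16 ± 0.36). A direct test of day 21 against day 3 called 10 features, with 7 positive and 3 negative differences, day 21 minus day 3. Cirbp (1.35 ± 0.28), Csrp2 (1.27 ± 0.23), the transcription factor Pou3f1 (1.20 ± 0.27), Map3k1 (0.96 ± 0.20) and Atp2b1 (0.90 ± 0.19) had positive differences, and Pvalb (−2.37 ± 0.51), Serpina3m (−1.23 ± 0.26) and Ampd1 (−1.19 ± 0.27) negative ones. Pvalb had −0.37 ± 0.34 at day 3, which did not pass. Pvalb and Ampd1 are expressed in muscle, the skeletal muscle list had a median of −1.88 in that test, and the array labelled Ch sham day 21 replicate 3 had the highest muscle score of all arrays (8.09). With the mean of the muscle list as a term, an alternative added after the data were seen, Pvalb (−1.94 ± 0.50) and Ampd1 (−0.82 ± 0.23) did not pass there and Serpina3m did (−1.32 ± 0.27). Without the 3 arrays that went against their labels the counts were 565 at day 3, 1056 at day 7 and 43 for the difference. The difference between days called 599 features without the low-level arrays, 1 in a fit to its own arrays, 1 without Ch day 21 replicate 1 and 156 without Ch sham day 3 replicate 2. After repeated quantile normalization it had 13 positive and 28 negative calls. In fits to the arrays of each contrast alone limma called 0 at day 3, with 816 at an unadjusted p under 0.05, and 9 at day 7. Leaving out the low-level arrays gave 0 calls at day 7 (242 at an unadjusted p under 0.05), where the array labelled sham replicate 1 was then the only sham array.

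CCI was compared with naive ganglia, and its few calls were led by the same injury genes. With 3 naive arrays as the only control its SEs were larger (0.40 for Atf3, against 0.28 after SNI). Its counts are therefore not at equal power with those of SNI and Ch, and a direct test of CCI against SNI called 19 features. Reg3b rose by 2.56 ± 0.41 (SE, 9 lesioned and 3 naive arrays, adjusted p = 4.44e-04), Npy by 2.53 ± 0.44, Atf3 by 2.35 ± 0.40 and Gal by 2.10 ± 0.37, and for each all 9 lesioned arrays lay above all 3 naive arrays. The regenerating gene Reg3a rose by 1.27 ± 0.29, the secreted neuronal protein gene Vgf by 1.25 ± 0.21, Ccl2 by 0.76 ± 0.16, the vesicle coat gene Sec31a by 0.64 ± 0.15, Ctxn1 by 0.54 ± 0.12 and Rab11b by 0.47 ± 0.10. Among named genes the largest fall was the ATP synthase subunit gene Atp5po at −0.39 ± 0.08. Its CCI arrays (10.88 to 11.23) overlapped the SNI sham arrays (10.94 to 11.24), and the naive arrays lay above both (11.33 to 11.46). The CCI mean contrast called 16 features, 14 rises and 2 falls, and all 12 called genes named for it moved in the same direction in each of the 9 arrays. Injury and regeneration genes rose in 5 of 37 cases, or 14 with 1 fall adjusted over the list alone. Injury genes had a camera adjusted p of 7.45e-23, and adjusted p = 0.0671 with an estimated correlation. Of 23 oxidative phosphorylation genes 1 fell, 6 adjusted over the list alone, with a list median of −0.18. Oxidative phosphorylation had a camera adjusted p of 1.67e-08, and adjusted p = 0.07 with an estimated correlation. Ccl2 was the single called member of 17 macrophage markers, 2 adjusted over the list alone. Macrophage markers had a camera adjusted p of 1.47e-05, and adjusted p = 0.137 with an estimated correlation. Camera also called the cytoskeleton list higher (adjusted p = 8.45e-05, median 0.11, adjusted p = 0.0858 with an estimated correlation) and the antigen presentation list higher (2.20e-04, median 0.15, adjusted p = 0.407 with an estimated correlation), although 0 of their members passed over all genes and 4 and 1 rose adjusted over the list alone.

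Schwann cell myelin markers lay lower after CCI, with a median of −0.14 (camera adjusted p = 0.00106, adjusted p = 0.137 with an estimated correlation), 0 members called over all genes and 4 falls and 1 rise adjusted over the list alone. Blood cell genes lay lower too, with a median of −0.35 and 0 of 9 members called by either adjustment. Blood cell genes had a camera adjusted p of 0.00702, and adjusted p = 0.394 with an estimated correlation. In the remaining lists 0 members were called and camera gave adjusted p-values of 0.766 for potassium channels, 0.569 for sodium, calcium and HCN channels, 0.388 for sensory neuron genes, 0.822 for transmitter receptors and 0.981 for satellite glia. The values were 0.198 for lymphocytes, 0.569 for matrix and for endothelial markers, 0.57 for muscle, 0.128 for adipose, 0.734 for cell cycle, 0.794 for cholesterol synthesis, 0.36 for tetrahydrobiopterin and 0.205 for heat shock genes. The list median, mean and test differed in sign after CCI for satellite glia, cholesterol synthesis and tetrahydrobiopterin genes. At single days CCI called 3 features at day 3, among them Reg3b (2.56 ± 0.51), Ccl2 (0.99 ± 0.20) and Capns1 (0.41 ± 0.07), 14 at day 7 and 9 at day 21. Capns1 was also higher in SNI sham arrays than in naive ones. At day 7 Npy (2.87 ± 0.53), Reg3b (2.76 ± 0.51), Atf3 (2.43 ± 0.49), Gal (2.27 ± 0.46) and Reg3a (1.59 ± 0.36) rose most. At day 21 Npy (3.44 ± 0.53), Gal (2.41 ± 0.46), Atf3 (2.37 ± 0.49), Reg3b (2.36 ± 0.51) and Vgf (1.19 ± 0.26) rose most and the cartilage collagen gene Col2a1 fell by 1.26 ± 0.26 and Atp5po by 0.48 ± 0.10. With SNI sham arrays as the control the mean contrast called 39 features, and Rab11b had −0.02 and did not pass. Of 27 called results of named genes in the CCI mean and single days, 12 stayed called with that control. Another 14 kept their sign but were no longer called, and 1 changed sign. The Schwann cell and blood lists had camera adjusted p-values of 0.069 and 0.301 with that control, and the potassium channel list passed at 1.68e-04. These values used the preset correlation, and an estimated correlation was not run with that control. A fit to the CCI and naive arrays alone called 94, a repeated quantile normalization 42, and the count was 6 without naive replicate 3.

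Kcns1, the gene named in the title of the series, was measured by 1 probe set with a mean log2 level of 7.53. Its level was 8.16 ± 0.35 (SD, n = 3) in naive ganglia and 8.26 ± 0.19, 8.00 ± 0.04 and 8.15 ± 0.10 in SNI sham ganglia of days 3, 7 and 21. After SNI it was 7.32 ± 0.36 at day 3, 7.50 ± 0.10 at day 7, 7.32 ± 0.25 at day 21 and 7.36 ± 0.21 at day 40. In the Ch groups it was 6.76 ± 1.04 at day 3, 6.12 ± 0.34 at day 7, 5.83 ± 0.02 (n = 2) at day 21 and 7.14 ± 0.86 at day 40, against 7.87 ± 0.14, 7.62 ± 0.91 and 8.00 ± 0.28 in the sham groups. Kcns1 fell after SNI by 0.76 ± 0.19, a 1.69-fold change with an adjusted p of 0.00826, and all 9 lesioned arrays lay below all 9 sham arrays. After Ch the fall was 1.59 ± 0.20, a 3.01-fold change with an adjusted p of 1.19e-07, in 7 of 8 lesioned arrays. In CCI the change was −0.40 ± 0.27 with an adjusted p of 0.981, in 9 of 9 arrays, and did not pass. By day the adjusted p-values were 0.214, 0.405 and 0.345 for SNI at days 3, 7 and 21 (log2 changes −0.94 ± 0.33, −0.49 ± 0.33 and −0.83 ± 0.33). They were 0.0637, 0.00388 and 1.47e-04 for Ch (−1.10 ± 0.33, −1.50 ± 0.33 and −2.17 ± 0.37). CCI gave −0.23 ± 0.33, −0.43 ± 0.33, −0.56 ± 0.33 and −0.43 ± 0.33 at days 3, 7, 21 and 40, with adjusted p-values from 0.498 to 1.0. The SNI effect minus the Ch effect was 0.83 ± 0.28 with an adjusted p of 0.153. Without the 3 Ch arrays that went against their labels the difference was 1.21 ± 0.16 and the Ch change −1.96 ± 0.12 for the mean, −1.70 ± 0.20 at day 3 and −1.50 ± 0.20 at day 40, and each of these passed. Kcns1 of these arrays itself went against their labels, so the values without them are no independent test of Kcns1. With naive arrays as the control the SNI value of −0.78 had an adjusted p of 0.102.

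**Figure D3:**
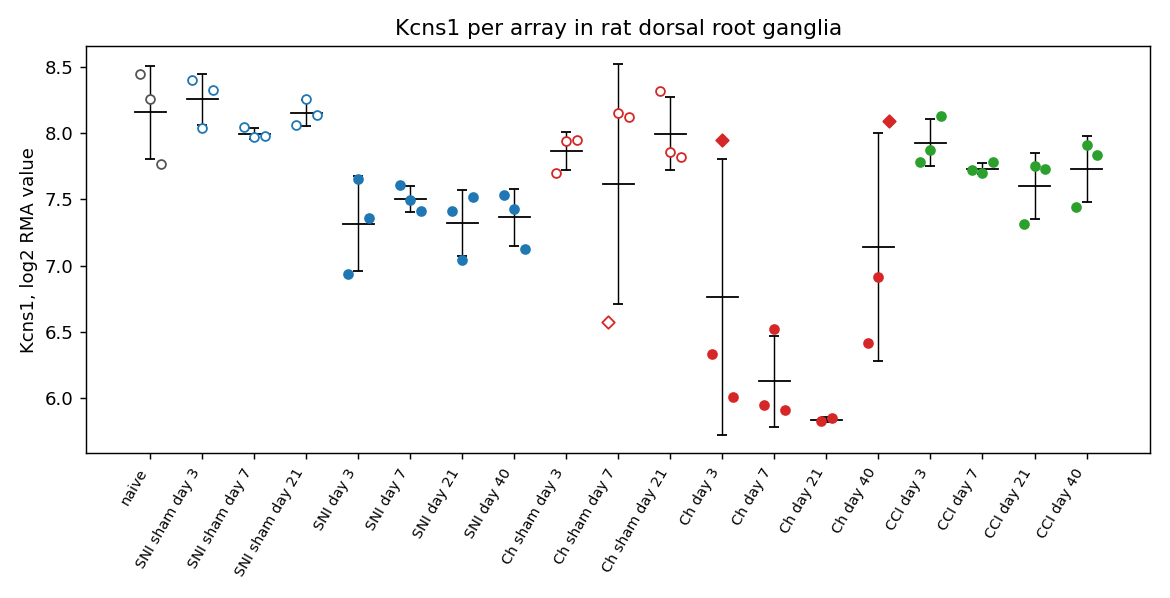
Log2 RMA value of Kcns1 per array and group, with open symbols for naive and sham arrays, filled symbols for lesioned arrays, diamonds for the 3 Ch arrays whose injury list mean went against their labels, and a bar with error bars for the group mean and SD. The 9 SNI arrays of days 3 to 21 lie between 6.94 and 7.66, all below the SNI sham arrays, which lie between 7.97 and 8.41.

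The study compared lesions for genes they share, and 9 features were called in the same direction in all 3. The 7 that rose were Npy, Reg3b, Atf3, Gal, Vgf, Ccl2 and Adissp, and those that fell were Atp5po and a probe set with no single gene name. Vgf rose by 1.02 ± 0.15 after SNI, 1.19 ± 0.16 after Ch and 1.25 ± 0.21 after CCI, and Ccl2 by 0.96 ± 0.11, 0.92 ± 0.12 and 0.76 ± 0.16. Adissp rose by 0.20 ± 0.05, 0.23 ± 0.05 and 0.34 ± 0.07, and Atp5po fell by 0.22 ± 0.06, 0.27 ± 0.06 and 0.39 ± 0.08. The CCI arrays overlapped the SNI shams, at 9.40 to 9.65 against 9.31 to 9.54 for Adissp and 10.88 to 11.23 against 10.94 to 11.24 for Atp5po. Naive arrays stood apart from those shams, at 9.14 to 9.16 and 11.33 to 11.46. The CCI changes of these 2 genes may thus hold a difference between naive and sham ganglia. Independent lists of these lengths would share 0.0815 rising and 0.00483 falling features. SNI and Ch shared 255 rises, where independent lists would share 37.7, and 107 falls, where independent lists would share 15.6. There were 0 features called in opposite directions. SNI and CCI shared 7 rises against 0.753 and 2 falls against 0.0683. Ch and CCI shared 9 rises against 1.51 and 2 falls against 0.141. The lesions shared no control arrays in these contrasts. The number called in all 3 was 40 without the 3 Ch arrays that went against their labels, 33 with SNI sham arrays as the control for CCI (which SNI and CCI then shared, so that calls in common can come from the control), 38 in fits to the arrays of each contrast alone, and 5 without naive replicate 1.

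The test of the difference between the SNI and Ch effects called 47 features, among them 4 of 34 sensory neuron, 4 of 22 cytoskeleton, 2 of 23 sodium, calcium and HCN channel, 2 of 45 transmitter receptor and 1 of 45 potassium channel genes. Sst had a difference of 2.15 ± 0.29 (adjusted p = 2.95e-05), Grik1 1.41 ± 0.31, Kcnd3 1.39 ± 0.25, Scn11a 1.33 ± 0.23 and Htr3a 1.20 ± 0.21, SNI minus Ch, and each of these had the more negative change after Ch. The other probe sets of Kcnd3 had −0.19 and −0.10 after SNI and −0.25 and −0.18 after Ch, so its difference rests on 1 probe set. On the other side were Pou3f1 (−0.77 ± 0.15), Myoc (−0.58 ± 0.14), the cyclin Ccnd3 (−0.54 ± 0.10), Csrp2 (−0.53 ± 0.13) and Pbsn (−0.37 ± 0.09). Pbsn had a low mean log2 level of 3.61. Its other probe sets had −0.19, −0.05 and 0.02 after SNI and 0.04, −0.04 and 0.10 after Ch. Those of Ccnd3 had −0.10, −0.16 and −0.10 after SNI and 0.33, −0.13 and 0.06 after Ch. In all, 36 differences were positive and 11 negative. The difference called 413 features without the 3 Ch arrays that went against their labels, 182 without Ch sham day 7 replicate 1 alone, 17 without Ch day 21 replicate 3 and 4 without the low-level arrays. CCI arrays set against SNI arrays of the same days gave 19 calls, 2 higher and 17 lower in CCI. Vip was lower by 1.69 ± 0.35, Gal by 1.26 ± 0.26, Serpina3n by 0.99 ± 0.21, the transglutaminase Tgm1 by 0.90 ± 0.16 and Csrp3 by 0.84 ± 0.17. The potassium channel subunit Kcng1 was higher by 0.47 ± 0.08 and Racgap1 by 0.46 ± 0.09. Kcns1 had 0.37 ± 0.19 in that contrast with an adjusted p of 0.634. The count was 94 in a fit to those arrays alone, 41 after repeated quantile normalization (10 higher, 31 lower) and 4 without CCI day 3 replicate 3.

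At day 40 the lesioned ganglia were compared with naive ones, and injury and regeneration genes rose in 8 of 37 cases in SNI, 17 in Ch and 1 in CCI. In SNI Npy rose by 3.73 ± 0.53, Reg3b by 2.92 ± 0.51, Atf3 by 2.83 ± 0.49, Vip by 2.61 ± 0.61 and Gal by 2.58 ± 0.46. Falls there included Col2a1 (−1.68 ± 0.26), Pvalb (−1.31 ± 0.34), the lipase Lpl (−1.03 ± 0.26), the myelin lipid enzyme Ugt8 (−0.81 ± 0.16) and Acot1 (−0.80 ± 0.16), among 62 calls (19 rises, 43 falls). In Ch Npy rose by 3.44 ± 0.53, Gal by 3.06 ± 0.46, Vip by 2.96 ± 0.61, Atf3 by 2.88 ± 0.49 and Cxcl14 by 2.35 ± 0.51. Its largest falls were Pvalb (−1.63 ± 0.34), Calb2 (−1.37 ± 0.23), Htr3a (−1.33 ± 0.26), Usp37 (−1.29 ± 0.40) and Vsnl1 (−1.27 ± 0.34), among 353 calls (217 rises, 136 falls). In CCI Npy rose by 2.27 ± 0.53, Ucp2 by 0.58 ± 0.12 and Capns1 by 0.34 ± 0.07. Ucp2 and Capns1 were higher by similar amounts in SNI sham arrays of earlier days against the same naive arrays, as given below. Genes that fell were led by Col2a1 (−1.61 ± 0.26), Cadps2 (−1.31 ± 0.31), Lpl (−1.07 ± 0.26), Mcm6 (−1.0 ± 0.24) and Ugt8 (−0.85 ± 0.16), among 34 calls (3 rises, 31 falls). Between days 40 and 3 of CCI 2 features were called, falls of Col2a1 by 1.31 ± 0.26 and of Ccl2 by 1.20 ± 0.20. Kcns1 did not pass at day 40 in SNI (−0.80 ± 0.33, adjusted p = 0.28) or Ch (−1.02 ± 0.33, adjusted p = 0.0598), where it passed without the array labelled Ch day 40 replicate 3 and the other 2 that went against their labels. The contrasts with naive arrays shared the same 3, which are labelled day 0. Time and age therefore cannot be told apart from the lesion in them. Against same-day shams Col2a1 had −0.60 ± 0.26, −0.29 ± 0.26 and −0.58 ± 0.26 at days 3, 7 and 21 of SNI. In Ch it had 0.07 ± 0.26, 0.40 ± 0.26 and 0.51 ± 0.29, and it passed at none of these days. Without naive replicate 1 limma called 12 for SNI and 0 for CCI (581 at an unadjusted p under 0.05). Ch called 811 without Ch day 40 replicate 3 and 3 in a fit to its own arrays. After repeated quantile normalization SNI had 57 rises and 42 falls and CCI 31 rises and 38 falls.

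Sham arrays were each compared with naive arrays, and these comparisons were not tested against each other over all genes. Ch sham arrays had Gal at 1.75 ± 0.37 above naive, Cxcl14 at 1.53 ± 0.42, Npy at 1.50 ± 0.44, Atf3 at 1.40 ± 0.40 and the class II chain Cd74 at 1.29 ± 0.22. The largest falls were the protease Adam10 (−1.06 ± 0.33), the mitochondrial fission gene Dnm1l (−0.99 ± 0.16), Vsnl1 (−0.97 ± 0.28), Slc24a2 (−0.92 ± 0.27) and the transferrin receptor Tfrc (−0.91 ± 0.15), among 371 calls with 84 rises and 287 falls. SNI sham arrays gave 10 calls, 9 rises and 1 fall, with Ucp2 at 0.60 ± 0.10, Dnm1 at 0.48 ± 0.09, Rab11b at 0.48 ± 0.10, Pfkl at 0.38 ± 0.09, Capns1 at 0.37 ± 0.06 and Alkbh7 at −0.38 ± 0.08. Kcns1 had −0.33 ± 0.27 in Ch sham and −0.02 ± 0.27 in SNI sham arrays and passed in neither. For Ch sham the count was 195 with a term for the low-level arrays (88 rises, 107 falls), 419 after repeated quantile normalization (154 and 265), 0 in a limma fit to its own arrays (1187 at an unadjusted p under 0.05) and 41 without naive replicate 2. SNI sham called 72 after repeated quantile normalization and 79 in a fit to its own arrays, and the order of the Ch and SNI sham counts was reversed in the fits to their own arrays.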

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

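The tests of a lesioned ganglion, of a sham injury, of muscle tissue, of the low-level arrays and of the array labelled Ch sham day 7 replicate 1 in the sham comparison were chosen only after the results were seen.

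The injury list mean, Atf3 and Kcns1 of 3 Ch arrays went against their labels. The array labelled Ch sham day 7 replicate 1 stood apart from the other Ch shams with an injury list mean of 8.32 and Kcns1 at 6.57. The array labelled Ch day 3 replicate 2 stood apart from the other lesioned Ch arrays with 7.64 and 7.95. On a score of 569 genes of the SNI effect, scaled to 0 for the other Ch shams and 1 for the other lesioned Ch arrays, the sham array had 0.741, which lay above the highest other sham (0.132) but below every lesioned array (lowest 0.833, SD 0.116). Ch day 3 replicate 2 and Ch day 40 replicate 3 had 0.167 and 0.0737. On genes that change with time the sham array had 1.19, nearest the day 40 mean of 1 but beyond it by more than the SD of 0.0859. An exchange with Ch day 40 replicate 3 predicted a value nearest day 40. The score was scaled on lesioned Ch arrays and no other sham or naive array was set on it. It therefore cannot tell an exchange from an injury during the sham operation, and Ch day 3 replicate 2 has no partner. An injury during the sham operation stays open, since 8 of 8 other Ch shams had Atf3 above every naive array (7.00 to 8.11 against 6.32 to 6.66) while 5 of 9 SNI shams did. Some other genes did not go against the labels. Serpina3n of the sham array (6.91) lay among the other shams (6.51 to 7.04) and not the other lesioned arrays (7.29 to 9.28), and its Reg3b (7.59) lay between them (up to 5.74 and from 7.82). Ch day 3 replicate 2 had Serpina3n at 7.31 and Ccl2 at 9.005, both among the lesioned arrays, and Reg3b at 7.69. These genes were picked after their values were seen and decide nothing by themselves. A less complete lesion could equally account for the other arrays and was not tested.

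Skeletal muscle genes differed widely between arrays of a group, with a muscle score from 5.55 to 8.09 over sham and lesioned arrays. Deviations of 18 muscle genes from their group means correlated at a mean r of 0.54 over arrays, across genes that are not independent replicates, against at most 0.189 in 100 random sets, consistent with muscle tissue taken along with some ganglia. The score differed between lesioned and sham arrays by −0.39 in SNI (exact two-sided permutation p = 0.14) and 0.22 in Ch (exact two-sided permutation p = 0.595), so a change with the lesion cannot be told apart from this spread.

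Ch sham arrays differed from naive arrays in 371 features, 287 of them lower. With a term for the low-level arrays, which were 4 of the 9 Ch shams and 0 of the naive arrays, 62 of 84 higher features stayed called. The same arrays had picked these features as higher, and the median probe set lay lower in the low-level arrays (difference −0.087). That count therefore does not decide whether mean level was their whole cause. Without the array labelled Ch sham day 7 replicate 1, 340 of 371 features stayed called. With that term and without that array together 96 were called, among them 42 of the 84 higher and 50 of the 287 lower features. Of the lower features 103 stayed called with the term alone. The mean of all 287, a test chosen after that count had decided neither way, moved from −0.506 ± 0.0717 to −0.425 ± 0.0581 (SE), and all 287 stayed negative. The same arrays had picked these features as lower, which favours a negative mean and is not covered by its SE. The mean therefore does not decide whether mean level was the whole cause of the falls. The calls ended as the changes became smaller and not as their SE grew (medians −0.47 and −0.40, SE 0.122 and 0.117). The low-level term on the mean of the lower features was −0.181 ± 0.0363 (SE), which goes with a share of mean level in the falls. Low-level Ch shams were among the arrays that picked these features, so the size of that share stays open. An injury response of the sham operation may account for part. Of the lower features 75.3% were negative in SNI, against 58.4% of all features, and of the higher ones 61.9% were positive, against 41.6% of all. By the bound of 75 set beforehand the lower features passed and the higher ones decided neither way. That bound took no account of the shares of all features, so it does not show that the lower features fit better than the higher ones.

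Mean level set apart SNI sham day 21 replicate 3 (6.32), SNI day 7 replicate 3 (6.30) and Ch day 7 replicate 1 (6.32) from the other arrays of their kind. In all 7 of 20 sets and measures held such an array, where chance gives about 1 in 20.

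The SNI and Ch effects differed in 47 features by a test of the difference. Sst differed by 2.15, Grik1 by 1.41, Kcnd3 by 1.39, Scn11a by 1.33, Htr3a by 1.20, Pou3f1 by −0.77, Myoc by −0.58, Ccnd3 by −0.54, Csrp2 by −0.53 and Pbsn by −0.37. The Kcnd3 difference rests on 1 of its probe sets. Pbsn had a low mean log2 level of 3.61, and the other probe sets of Pbsn and Ccnd3 differed less between the lesions. The Ch effect at days 21 and 3 differed in 10 features, with Cirbp at 1.35, Csrp2 at 1.27, Pou3f1 at 1.20, Map3k1 at 0.96, Atp2b1 at 0.90, Pvalb at −2.37, Serpina3m at −1.23 and Ampd1 at −1.19.

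Other splits of the same arrays were counted, the real split included. Of 100 drawn splits 1 gave as many calls as the SNI mean (569, highest other 256), the Ch mean (1157, 614), the CCI mean (16, 1), CCI against SNI (19, 0) and the genes called in all 3 lesions (9, 0). That 1 was the real split, the smallest share that 100 splits can give, which argues against chance alone for these counts. The splits for all 3 lesions exchanged arrays in every lesion at once, so they do not test whether the overlap by itself exceeds chance. For SNI sham 2 of 100 splits gave as many calls (10, highest other 15) and for Ch sham 2 (371, 519). Both shares lay under the 0.05 set beforehand, but in each another split gave more calls than the real one, so chance is not excluded there. The split with 519 calls placed 3 low-level Ch shams as naive, and 195 were called with the low-level term. For SNI minus Ch 3 of 100 splits gave 47 or more and the highest gave 810, which points to a structure of the samples. Its source was not identified, and the 3 Ch arrays that went against their labels and the low-level arrays were among those split. For SNI day 21 minus day 3, with 0 limma calls and 222 at an unadjusted p under 0.05, 100 of 100 splits gave as many (highest other 1). Groups of 3 against 3 make 10 splits, too few for a share under 0.05. There the real and highest other counts were 65 and 2 for SNI day 3, 153 and 0 for SNI day 7, 43 and 1 for SNI day 21, 460 and 363 for Ch day 7, 62 and 0 for SNI day 40, 3 and 0 for CCI day 3, and 14 and 0 for CCI day 7. They were 9 and 0 for CCI day 21, 34 and 0 for CCI day 40, and 2 and 0 for CCI day 40 against day 3, with 1 split as large. For Ch day 3 3 splits were as large (132, highest 189, exchanging Ch day 3 replicate 2 with sham day 3 replicate 2) and for Ch day 40 2 (353, highest 436, exchanging Ch day 40 replicate 3 with naive replicate 1).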

How the results depend on the processing

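The tests with a term for the low-level or muscle signal, without the low-level arrays and without the 3 Ch arrays that went against their labels were chosen only after the data were seen, and the others before. All values are counts of called features unless another quantity is named, beside the counts in the results, and the cause of a change was not tested unless fewer arrays or features explain it by construction. The Ch mean and SNI mean counts stayed within 1.5 times of 1157 and 569 whichever single array was left out, and Kcns1 after SNI and Ch kept its sign under every alternative run and was called under each except after SNI with naive arrays as the control. With the mean of all probe sets of a gene, limma called 5 for CCI day 21, 30 for CCI against SNI and 1 for CCI day 40 against day 3. With features of low mean level removed, limma called 5 for CCI day 3, 100 for CCI day 40 and 16 for SNI sham. After another quantile normalization, limma called 105 for SNI day 3, 235 for SNI day 7, 200 for Ch day 3, 33 for CCI day 7 and 23 for CCI day 21. Counts were 69 for CCI day 40, 42 for the CCI mean, 99 for SNI day 40, 72 for SNI sham and 75 for SNI minus Ch. Counts were 41 for CCI against SNI, 41 for Ch day 21 minus day 3, 1 for CCI day 40 against day 3 and 16 for all 3 lesions. In fits to the arrays of a contrast alone, limma called 79 for SNI day 21, 0 for Ch day 3 (816 at an unadjusted p under 0.05), 9 for Ch day 7, 748 for the Ch mean and 8 for CCI day 7. Counts were 50 for CCI day 21, 0 for CCI day 40 (1292 at an unadjusted p under 0.05), 94 for the CCI mean, 41 for SNI day 40 and 3 for Ch day 40. Counts were 79 for SNI sham, 0 for Ch sham (1187 at an unadjusted p under 0.05), 15 for SNI minus Ch, 94 for CCI against SNI and 1 for SNI day 21 minus day 3. Counts were 1 for Ch day 21 minus day 3, 1 for CCI day 40 against day 3 and 38 for all 3 lesions. With naive arrays as the control, limma called 101 for SNI day 3, 74 for SNI day 21, 240 for the SNI mean and 765 for Ch day 3. Counts were 1088 for Ch day 7, 1028 for Ch day 21 and 15 for all 3 lesions. With SNI sham arrays as the control, limma called 1 for CCI day 3, 2 for CCI day 7, 4 for CCI day 21, 39 for the CCI mean and 33 for all 3 lesions, where as with naive arrays some lesions shared their control. With a term for the low-level arrays, limma called 23 for SNI day 21, 22 for CCI day 40, 26 for SNI sham and 195 for Ch sham. Counts were 41 for CCI against SNI, 47 for Ch day 21 minus day 3 and 1 for CCI day 40 against day 3. With the low-level arrays left out, limma called 250 for Ch day 3, 0 for Ch day 7 (242 at an unadjusted p under 0.05), 337 for the Ch mean, 4 for CCI day 40 and 33 for SNI day 40. Counts were 32 for SNI sham, 4 for SNI minus Ch, 36 for CCI against SNI, 599 for Ch day 21 minus day 3 and 1 for CCI day 40 against day 3. Without the 3 Ch arrays that went against their labels, limma called 565 for Ch day 3, 1056 for Ch day 7, 906 for Ch day 40, 413 for SNI minus Ch, 43 for Ch day 21 minus day 3 and 40 for all 3 lesions. With the muscle list as a term, limma called 201 for Ch day 3, 286 for Ch day 7, 14 for CCI day 21 and 242 for CCI day 40. Counts were 30 for SNI sham, 84 for SNI minus Ch, 5 for Ch day 21 minus day 3 and 6 for CCI day 40 against day 3. The 3 arrays had been picked from their injury genes and Kcns1 went the same way in them, so counts and Kcns1 values without them are not independent evidence. Splits of rises and falls moved by over 10 points after another quantile normalization to 31 and 38 for CCI day 40, 57 and 42 for SNI day 40 and 154 and 265 for Ch sham. They moved to 10 and 31 for CCI against SNI and 13 and 28 for Ch day 21 minus day 3, and with the low-level term to 530 and 525 for the Ch mean and 88 and 107 for Ch sham.

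Leaving out each array in turn gave 26 to 60 for SNI day 3, 40 to 185 for SNI day 7, 14 to 25 for SNI day 21, 4 to 439 for Ch day 3 and 77 to 909 for Ch day 7. Counts were 190 to 471 for Ch day 21, 0 to 5 for CCI day 3, 0 to 23 for CCI day 7, 1 to 4 for CCI day 21 and 0 to 166 for CCI day 40. Counts were 6 to 20 for the CCI mean, 12 to 51 for SNI day 40, 80 to 811 for Ch day 40, 3 to 20 for SNI sham and 41 to 440 for Ch sham. Counts were 17 to 182 for SNI minus Ch, 4 to 25 for CCI against SNI, 1 to 156 for Ch day 21 minus day 3 and 0 to 9 for CCI day 40 against day 3 and 5 to 13 for all 3 lesions. SNI day 21 minus day 3 stayed at 0 calls by limma throughout (222 at an unadjusted p under 0.05 with all arrays). A group left with a single array was assumed to vary like the others. Kcns1 ranged from −0.81 to −0.69 after SNI, −1.79 to −1.46 after Ch and −0.60 to −0.26 after CCI. With naive arrays as the control Kcns1 after SNI was −0.78 and no longer called. Of 26 list tests called at the preset correlation 1 was called with an estimated correlation. The muscle list turned direction with the other control, at camera adjusted p-values of 0.995 in SNI and 0.0151 in CCI, both at the preset correlation alone. Rab11b after CCI was −0.0174 against SNI sham arrays. Kcns1 in SNI sham against naive, not called at any setting, was 0.0439 after another quantile normalization and −0.22 to 0.13 with single arrays left out, and its SNI effect at day 21 minus day 3 was −0.0799 to 0.278. Acta1 after SNI was 0.0469 against naive arrays and 0.18 with the muscle term, where Ckm was 0.0858, and neither was called.

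No label says that the replicate numbers pair the samples, and the main model did not take them to do so. Not every pair of arrays with the same number deviated together, which does not exclude a factor shared by many of them. Deviations from group means had a mean correlation of 0.0721 and a lowest of −0.594 at the same number, with 45.3% of 495 pairs over 0.1, and a mean of −0.0363 at different numbers. The best match of 29 of 56 arrays had their own number, against 18.7 by chance, a hint from the data that arrays of a number share something. With the replicate number as a block limma called 259 for SNI day 7, 5 for CCI day 3, 206 for CCI day 40 and 25 for the CCI mean. Counts were 43 for SNI sham, 36 for CCI against SNI, 22 for Ch day 21 minus day 3 and 4 for CCI day 40 against day 3. The depth of an array is its signal over background, which was not used here.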

Other observations

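The day-by-day values and the exclusion of low-level arrays here were chosen only after the results were seen.

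Counts of called genes by day differed between the antigen presentation and complement list and the injury list, and the lists were not tested against each other. After SNI 0 of 21 rose by limma's adjusted test at day 3, 7 at day 7 and 2 at day 21, while injury and regeneration genes rose in 18, 19 and 14 of 37 cases. After Ch the counts were 0, 5 and 14 of 21 for antigen presentation and complement and 9, 25 and 24 of 37 for injury genes. The class II genes RT1-Da and Cd74 had 0.43 ± 0.30 and 0.37 ± 0.27 at day 3 of SNI and did not pass, and rose by 1.79 ± 0.30 and 1.71 ± 0.27 at day 7 and by 1.37 ± 0.30 and 1.46 ± 0.27 at day 21. The complement gene C1qb of the same list had 1.03 ± 0.28 at day 3 of SNI and 1.06 ± 0.28 at day 21, which did not pass, and rose by 1.37 ± 0.28 at day 7. In Ch the complement gene C3 rose by 1.65 ± 0.32 at day 21, after 0.45 ± 0.28 and 0.59 ± 0.28 at days 3 and 7, which did not pass. The chemokine gene Ccl2 rose at each day of SNI, by 1.13 ± 0.20, 0.75 ± 0.20 and 0.99 ± 0.20. The tests of day 21 against day 3 called 0 members of the antigen list in either lesion, so a difference between days was not shown. Sst had 0.00 ± 0.35, 0.14 ± 0.35 and 0.09 ± 0.35 at days 3, 7 and 21 of SNI, and 0.31 ± 0.35, 0.34 ± 0.35 and 0.27 ± 0.35 in CCI, and passed at none of them.

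A hypothesis drawn from Atf3, which was higher in Ch shams than in SNI shams, was that the Ch sham operation induces injury genes beyond the SNI sham operation. It was tested in the same sham arrays, and so not independently of Atf3. The test used 35 injury genes without Atf3 and Gal and left out the array labelled Ch sham day 7 replicate 1. Their mean was 7.39 ± 0.14 (SD, n = 8) in Ch shams and 7.27 ± 0.06 (SD, n = 9) in SNI shams, a difference of 0.13 with an exact two-sided permutation p of 0.0186. Without the low-level arrays the difference was 0.23 with an exact two-sided permutation p of 0.00202 (n = 4 and 8). The 4 low-level Ch shams had the lowest injury list means of the 8 (7.24 to 7.37, against 7.50 to 7.70). Leaving them out therefore raises the difference, no Ch sham of day 7 is left, and that p is the smallest the test can give. The higher mean in Ch shams goes with the hypothesis. A difference in processing between the Ch and SNI arrays could give the same result, since no label separates them.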
